A study of Oryza sativa with 12 samples.

How the data were processed

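Shoots of T65, gid1-3, gid2-1 and slr1 (k1001), grown in a greenhouse and harvested 5 weeks after germination, were profiled with 3 biological replicates per line on an Affymetrix rice array. Per the labels, total RNA was extracted with a column kit and processed to biotinylated cRNA. The deposited values are probe-set signals in the unit intensity, on a linear scale. The software that made them is not stated, and the table holds no detection calls. On every array the mean after trimming 2% of probe sets at each end was 500.1, which a single scaling factor per array by the authors would give.

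The table held 57381 probe sets, of which 187 controls were left out, so that 57194 were tested. Signals under 1 were set to 1 and log2 was taken, with no further normalization. A model with 1 mean per line was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend in the prior variance), and p values were adjusted by Benjamini and Hochberg over all tested probe sets. A probe set was called at an adjusted p under 0.05. The comparisons were each mutant against T65, gid1-3 against gid2-1, slr1 against the mean of gid1-3 and gid2-1, and an F-test over the 3 contrasts with T65. Replicate numbers were not used as blocks, since the labels do not pair them. Of 12 arrays, 4 correlated best with an array of their own number in another line, after line means were subtracted. Such correlations ran from -0.28 to 0.21 for same-number pairs, with 4 of 18 over 0.1. For other pairs they ran from -0.28 to 0.27, with 4 of 36 over 0.1.

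Overlaps of calls were set beside the number expected of independent lists and beside 50 simulations of unchanged groups against the same T65 arrays. In a further fit no T65 array was shared: 1 served as the control of the gid mutants and the other 2 as that of slr1, for each choice of that array. A control of 1 array has no spread of its own, so the spread in that fit came from the other arrays. Precision is limited by the 3 arrays per line. Data were simulated for gid1-3 against T65 with 200 changed of 57194 probe sets, all of them at or above the median T65 signal. The fit recovered 37.3% of changes of log2 0.5, 82.1% of 1 and 93.9% of 2, with 9 false calls and 0 calls in an unchanged gid2-1. These shares do not cover dim probe sets. They also do not apply at the call rates of the data, 19.9 to 30% of probe sets, where the adjusted threshold is less strict.

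Probe sets were paired with genes through the array's table, which named 1 gene for 22436 of them, several for 95 and none for 34663. This gave 17905 genes, all found in the reference gene table, of which 2460 had a name other than a LOC number or clone name. A gene was represented by its probe set with the highest mean. No genome came with the reference, so no coordinates are given.

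The 34 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. Of these lists 14 were of loci, and 62 of the 96 listed loci were matched by name to a gene on the array. For 24 the name was not in the gene table, among them GA20ox1, both GA3ox genes and the GA2ox genes, for 9 no probe set was paired with the gene, and 1 lay on another chromosome. The other 20 lists were to be matched to gene descriptions, which the reference lacks, so patterns for symbols and synonyms were written after the tables were seen and before any test of expression. For the same reason the rule's description of a gene was replaced by a name other than a LOC number or clone name. Lists with at least 4 measured members were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

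Genes were named by this rule: GID1, GID2 and SLR1; for each comparison the 10 largest rises and 10 largest falls among called probe sets with a named gene, no overlap between the arrays of both sides and a mean at or above the median; for each list and mutant up to 4 members with the smallest p; and 10 genes in each direction among those with opposite signs in the gid mutants and slr1. Other list members given as examples were chosen after their values were seen.

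Alternatives were quantile normalization, centring of arrays on their medians, leaving out dim probe sets, no trend in the prior variance, only the arrays of the lines compared, a replicate block, a threshold of 2-fold, leaving out probe sets that can cross-hybridize, a pseudocount of 16, averaging a gene's probe sets, and leaving out each array in turn. Centring on the spiked controls was added after the data were seen. Where the number of settings that end a gene's call is given, the 2-fold threshold is not counted. The probe sets of HSP18.6, EXLA2, OSH43, SGR, SAPK9 and CLPB-M are among those that can bind related transcripts. Sequence-level checks were not possible, since the table holds no probe values.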

Results

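Transcript levels were measured in shoots of 4 rice lines with an Affymetrix rice array. The lines were Taichung 65 (T65), the parental cultivar, and 3 mutants of gibberellin signalling: gid1-3, gid2-1 and slr1 (k1001). GID1 is the soluble gibberellin receptor, GID2 is the F-box protein through which the DELLA repressor is degraded, and SLR1 is the rice DELLA repressor itself. Plants were harvested 5 weeks after germination, and each line was measured on 3 arrays, 1 per biological replicate, for 12 arrays in all. The labels do not say whether the slr1 allele has lost or gained function. The median signal of the 57194 probe sets tested ran from 58.0 to 75.8 over the 12 arrays, and 54.7 to 63.1% of them lay above the signal of the array's reporter controls (95th percentile). The number of arrays limits the precision. The median coefficient of variation of the brighter probe sets was 6.23% in T65, 7.64% in gid1-3, 10.2% in gid2-1 and 8.86% in slr1. Signals below are scaled linear intensities given as mean ± SD with n = 3, log2 changes are given ± SE, and adjusted p values are from limma. Mean signals of EXPA1, LAC4, RCN1 and OSH43 in gid1-3, of HSP16.0, HSP18.6, RAB16B and OSH43 in gid2-1 and of PCL1 and ABCG45 in slr1 lay below the highest reporter level of the line's arrays (52.2, 52.1 and 51.6), so the size of their falls is not resolved. Genes quoted with the largest changes of a comparison had all arrays of one side above all arrays of the other.

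The transcripts of the mutated pathway itself differed between the lines. GID1 signal was 4494 ± 48.1 in T65, 6407 ± 165 in gid1-3 (log2 change 0.51 ± 0.06, adjusted p = 3.4e-06), 6112 ± 432 in gid2-1 (0.44 ± 0.06, adjusted p = 1.9e-05) and 2461 ± 5.39 in slr1 (-0.87 ± 0.06, adjusted p = 3.1e-08). SLR1 signal was 1295 ± 60.3 in T65 and fell to 827 ± 10.4 in gid1-3 (-0.65 ± 0.06, adjusted p = 8.1e-07). In slr1 the SLR1 signal was 1565 ± 82.5 (0.27 ± 0.06, adjusted p = 0.0051), a call lost with arrays centred on their medians or on the spiked controls. The SLR1 change in gid2-1 was -0.19 ± 0.06 (adjusted p = 0.036), a call lost under 8 other settings. The reference entry matched to GID2 also carries the name of a 14-3-3 protein, GF14E, so its values, lower in gid1-3 (-0.70 ± 0.07) and gid2-1 (-0.53 ± 0.07), could belong to either gene. None of these signals tests whether a mutation is present.

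Some genes of gibberellin synthesis rose in both gid mutants. GA20ox3, a GA 20-oxidase of the late steps, measured 848 ± 74.2 in T65, 2269 ± 75.2 in gid1-3 and 1637 ± 48.2 in gid2-1 (log2 changes 1.42 ± 0.07, adjusted p = 8.7e-10, and 0.95 ± 0.07, adjusted p = 9.3e-08), and fell to 508 ± 35.0 in slr1 (-0.74 ± 0.07, adjusted p = 3.1e-06). GA20ox2, the semi-dwarf gene, rose in gid1-3 from 289 ± 35.0 to 1090 ± 78.7 (1.92 ± 0.15, adjusted p = 6.7e-08), with 384 ± 61.9 in gid2-1 and 316 ± 60.3 in slr1, neither of them called. CPS1, the first committed enzyme, fell in gid1-3 (-0.97 ± 0.12) and gid2-1 (-1.28 ± 0.12). Of the 6 measured synthesis genes, 4 rose and 1 fell in gid1-3, 3 rose and 1 fell in gid2-1, and 3 rose and 1 fell in slr1; adjusted over the list alone the counts were the same except for 4 higher in gid2-1. The rise of KS1, 1 of these genes, in slr1 was lost with arrays centred on their medians or on the spiked controls and without a trend in the prior variance. It was also lost without any 1 of the T65 arrays and without replicate 2 or 3 of slr1. The list as a set did not pass limma's camera test in the 3 comparisons (adjusted p = 0.096, 0.42 and 0.5). Of the 6 signalling genes, 2 rose and 3 fell in gid1-3, 2 rose and 2 fell in gid2-1, and 1 rose and 1 fell in slr1 (camera adjusted p = 0.53, 0.89 and 0.79); adjusted over the list alone, 4 were lower in gid2-1. The only gibberellin-inactivating enzyme that could be named on the array, EUI1, fell in gid1-3 (-1.12 ± 0.29, adjusted p = 0.0083) and in gid2-1 (-0.85 ± 0.29, adjusted p = 0.047, lost under 11 other settings), and measured -0.31 ± 0.29 in slr1 (adjusted p = 0.59).

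**Figure D1:**
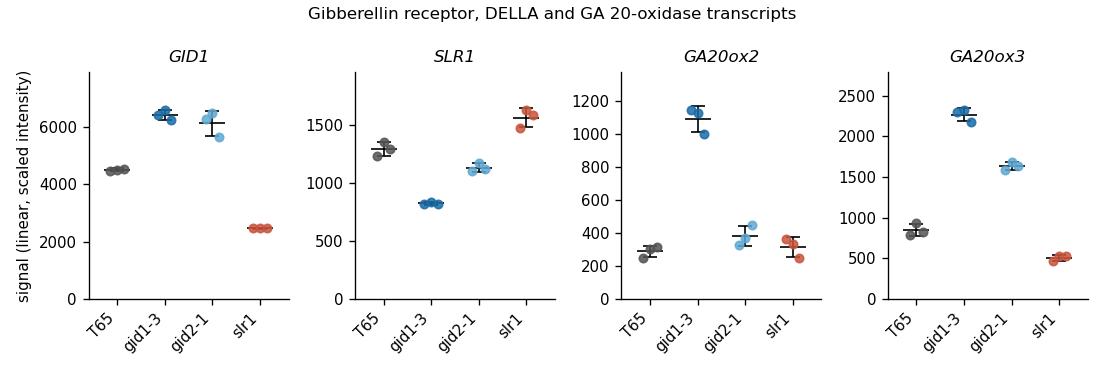
Signal (linear scaled intensity, y axis) of GID1, SLR1, GA20ox2 and GA20ox3 in each line (x axis), with points for the 3 arrays and bars for the mean ± SD. GID1 and GA20ox3 lie above T65 in both gid mutants and below it in slr1, where GID1 averages 2461 against 4494 in T65.

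In gid1-3, which carries a mutation of the receptor, all 6 listed cellulose synthases were below T65. The cellulose synthases of the secondary wall, CESA4, CESA7 and CESA9, fell from 4103 ± 58.7 to 435 ± 43.4, from 4200 ± 341 to 376 ± 117 and from 1448 ± 42.3 to 133 ± 14.6. EXPA1, an expansin that loosens cell walls, fell from 311 ± 20.3 to 8.28 ± 3.20, and LAC4, a laccase of lignin formation, from 1390 ± 64.0 to 32.0 ± 23.1, while LAC24, another laccase, rose. BURP16, a BURP-domain protein, rose from 130 ± 31.9 to 12720 ± 577. An oxophytodienoate reductase of the jasmonate family, 1 of 2 genes named OPR4, rose from 40.0 ± 4.02, which lies below the highest reporter level of the T65 arrays (42.0), to 716 ± 115.

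Of 29 expansins, 18 fell in gid1-3, 2 rose and 9 were not called, the same counts as adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.095 with an estimated correlation). EXPA2 and EXPB11 fell (log2 changes -3.23 ± 0.09 and -2.83 ± 0.11), while EXLA1 and EXLA2, expansin-like genes, rose by 0.86 ± 0.06 and 1.15 ± 0.09. All 3 secondary-wall and all 3 primary-wall cellulose synthases fell, with medians of -3.45 and -1.29. Among 17 cyclins and CDKB kinases of the cell cycle, 12 fell, 2 rose and 3 were not called, or 13 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.11 with an estimated correlation). CYCB1-1, a mitotic cyclin, measured 1256 ± 26.2 in T65 and 257 ± 24.2 in gid1-3. Of 10 tubulins, 8 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.0055; adjusted p = 0.11 with an estimated correlation). Replication licensing genes counted 6 lower and 1 higher of 9 (camera adjusted p = 0.13), and core histones, here 5 H2B genes, 3 lower and none higher (0.36). Of these histones H2B.6 and H2B.10 lost their calls with arrays centred on their medians, without a trend in the prior variance and without replicate 2 of T65 or of gid1-3. H2B.10 also lost its call without replicate 1 of T65 or replicate 3 of gid1-3. In the monolignol and laccase list 13 fell and 5 rose of 24 (camera adjusted p = 0.22), and in the Aux/IAA and SAUR list of auxin response 13 fell and 6 rose of 27 (0.24). Of 4 KNOX genes 3 fell (camera adjusted p = 0.098), with OSH1 going from 1214 ± 62.2 to 436 ± 14.6.

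Of 35 genes of jasmonate synthesis and TIFY repressors, 18 rose in gid1-3, 5 fell and 12 were not called, or 19 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.16 with an estimated correlation). The lipoxygenase LOX8 went from 2882 ± 142 to 12640 ± 454. In the list of chitinases and glucanases, which held 13 chitinases, 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0055; adjusted p = 0.095 with an estimated correlation). Of 11 genes of diterpenoid phytoalexins, antimicrobial compounds of rice, 6 rose and 2 fell (camera adjusted p = 0.084; adjusted p = 0.2 with an estimated correlation; 0.025 with arrays centred on their medians), among them KSL10 with 194 ± 53.9 in T65 and 1291 ± 25.5 in gid1-3. Heat shock genes counted 5 higher and 8 lower of 23 (camera adjusted p = 0.6). The largest rises included CIPK14, a protein kinase (4.01 ± 0.08), NAC45, a transcription factor (3.80 ± 0.12), and NSHB2, a haemoglobin (3.63 ± 0.25); the largest falls included the transporter RCN1 (-5.04 ± 0.29), CRSH2 (-4.91 ± 0.24) and PMEI8, a pectin methylesterase inhibitor (-3.77 ± 0.14). Of the 57194 probe sets, 8068 were higher and 8810 lower in gid1-3 than in T65 at an adjusted p under 0.05, and 6385 of these 16878 changed at least 2-fold. With each array centred on its spiked controls, a scaling chosen after the data were seen that moved the median log2 change by -0.22, the split was 4716 higher and 11749 lower. With all 12 arrays centred on their medians it was 7256 higher and 6576 lower.

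**Figure D2:**
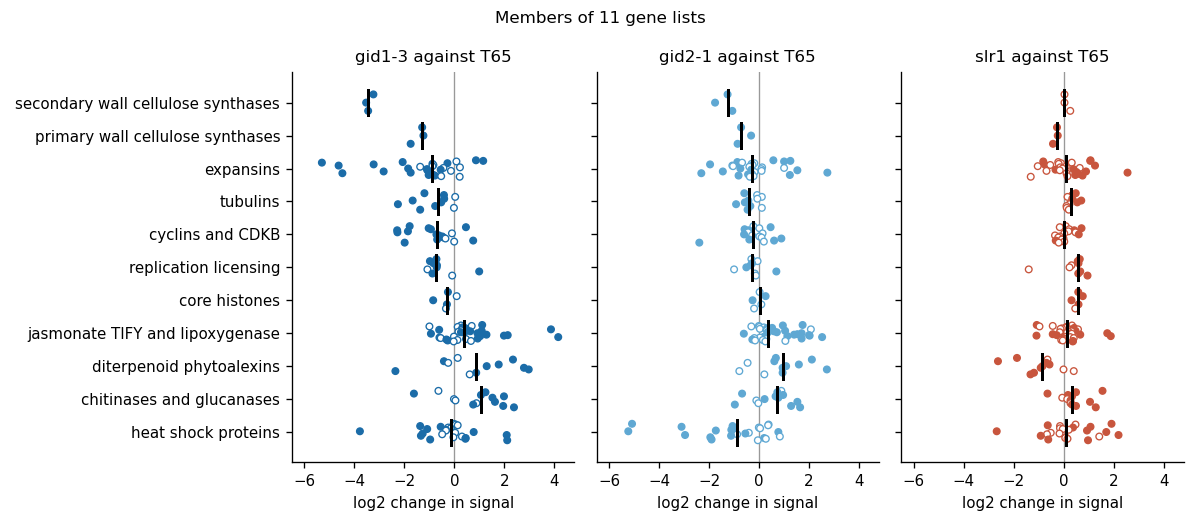
Log2 change in signal (x axis) of the members of 11 gene lists (y axis) in each mutant against T65, with filled points for genes called, open points for genes not called and bars for the list's median. The secondary-wall cellulose synthases have medians of -3.45 in gid1-3, -1.26 in gid2-1 and 0.03 in slr1, and the diterpenoid phytoalexins of 0.87, 0.94 and -0.85.

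In gid2-1, the F-box mutant of the complex that marks DELLA proteins for degradation, the tonoplast aquaporin TIP1 fell 84.8-fold, to 81.2 ± 3.86 in gid2-1 (log2 change -6.41 ± 0.06, adjusted p = 2.2e-17), and the plasma-membrane aquaporin PIP1-3 fell from 7129 ± 86.7 to 405 ± 40.4. PSY2, a phytoene synthase of carotenoid formation, fell from 4335 ± 67.1 to 197 ± 5.10. GLT2 rose 42.5-fold, from 167 ± 24.1 to 7057 ± 365, and BURP16 rose from 130 ± 31.9 to 4667 ± 226. Clock genes differed as well: LHY, a morning gene, fell from 13630 ± 535 to 2994 ± 68.6 (-2.19 ± 0.06, adjusted p = 1.7e-12), and the evening genes PRR1 and PCL1 rose by 1.33 ± 0.08 and 3.02 ± 0.41.

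Of 35 jasmonate genes, 19 rose, 2 fell and 14 were not called in gid2-1, or 22 higher and 2 lower adjusted over the list alone (camera adjusted p = 2e-04; adjusted p = 0.15 with an estimated correlation). LOX9 rose from 1972 ± 25.2 to 7986 ± 533, and an allene oxide synthase, 1 of 2 genes named AOS, from 2330 ± 104 to 7779 ± 356. Of 11 phytoalexin genes 8 rose and none fell, or 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.035; adjusted p = 0.18 with an estimated correlation; 0.051 with a gene's probe sets averaged and 0.062 without replicate 1 of gid2-1). KSL4, a diterpene synthase, was 6.55-fold higher. NH1, a regulator of salicylate responses, rose by 1.40 ± 0.10 in gid2-1 and by 1.04 ± 0.10 in gid1-3, while PR10a, the other measured defence marker, fell by 0.43 ± 0.06 in gid1-3 and was not called in gid2-1. Of 13 chitinases 8 rose and 2 fell (camera adjusted p = 0.12), and of 6 WRKY factors 4 rose and none fell (0.12; in gid1-3 4 rose and 1 fell, 0.2). Heat shock genes counted 12 lower and 2 higher of 23, also adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.15 with an estimated correlation). Among these heat shock genes the largest estimated falls were those of HSP18.6 (-5.23 ± 0.24), whose probe set can bind related transcripts, and HSP16.0 (-5.08 ± 0.44). Both fell to signals below the reporter level, so the sizes are not resolved. Among 7 genes of abscisic acid and dehydration 5 fell and 1 rose (camera adjusted p = 0.12), as RAB16B, a dehydrin (-3.08 ± 0.26); in gid1-3 5 fell and none rose (0.091).

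All 3 secondary-wall cellulose synthases fell in gid2-1 (CESA4 -1.26 ± 0.07, CESA7 -1.76 ± 0.21, CESA9 -1.07 ± 0.13), as did all 3 primary-wall ones, and 6 of 10 tubulins fell with none higher (camera adjusted p = 0.12). Expansins counted 9 lower and 6 higher of 29 (0.49), cyclins and CDKB 6 lower and 3 higher of 17 (0.62), replication licensing 3 lower and 1 higher of 9 (0.49), core histones 1 lower and 1 higher of 5 (0.91), monolignol and laccase genes 9 lower and 5 higher of 24 (0.46), and auxin genes 7 lower and 4 higher of 27 (0.78). The KNOX genes OSH6 and OSH71 rose by 0.75 ± 0.13 and 0.58 ± 0.08, and OSH43 fell (camera adjusted p = 0.78, with a positive median and a negative mean). The calls of the replication and histone genes in gid2-1 were not stable: the 3 lower replication genes, MCM4, MCM5 and MCM7, were all lost without replicate 3 of T65, the higher MCM9 with centring on the spiked controls, and both histone calls, H2B.5 and H2B.11, without replicate 1 of T65. PSAG, a photosystem I subunit, fell from 4946 ± 356 to 814 ± 59.0, the only member of 5 photosynthesis genes called (camera adjusted p = 0.42). Of the probe sets, 7836 were higher and 7103 lower in gid2-1 than in T65, and 4919 of these 14939 changed at least 2-fold. Centred on the spiked controls, with a median log2 change of -0.15, the split was 4682 higher and 9676 lower; centred on array medians it was 5424 higher and 6189 lower.

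In slr1, the mutant of the DELLA repressor, CYP71Z7, a cytochrome P450 of the phytoalexin cluster, fell from 1727 ± 10.9 to 279 ± 28.4. PCNA, the replication clamp, rose from 878 ± 29.9 to 1695 ± 57.4, and TUBB6, a beta-tubulin, from 5231 ± 299 to 8519 ± 953. ICL, isocitrate lyase of the glyoxylate cycle, fell 24.6-fold, from 3604 ± 142 to 148 ± 25.9. The metal transporter Nramp1 rose from 327 ± 34.8 to 1944 ± 47.5 and the nicotianamine synthase NAS2 from 130 ± 28.0 to 634 ± 36.4.

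Of 11 phytoalexin genes 8 fell in slr1 and none rose, or 9 lower adjusted over the list alone (camera adjusted p = 0.0094; adjusted p = 0.11 with an estimated correlation). Of 10 tubulins 5 rose and none fell, or 8 higher adjusted over the list alone (camera adjusted p = 0.0094; adjusted p = 0.11 with an estimated correlation; 0.082 after quantile normalization and 0.083 with a gene's probe sets averaged). Replication licensing genes counted 6 higher and none lower of 9, or 7 higher adjusted over the list alone (camera adjusted p = 0.0094; adjusted p = 0.14 with an estimated correlation). All 5 H2B histone genes lay above T65, 4 of them called and 5 adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.23 with an estimated correlation). The call of H2B.5 was lost after quantile normalization, with arrays centred on their medians or on the spiked controls, and without a trend in the prior variance. It was also lost without any 1 of the T65 arrays and without replicate 1 or 2 of slr1. Of 13 chitinases 9 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.01; adjusted p = 0.11 with an estimated correlation). Expansins counted 11 higher and 3 lower of 29 (0.19), cyclins and CDKB 3 higher and 1 lower of 17 (0.61), auxin genes 10 higher and 3 lower of 27 (0.11), jasmonate genes 7 higher and 4 lower of 35 (0.27), heat shock genes 7 higher and 4 lower of 23 (0.26), monolignol and laccase genes 5 higher and 8 lower of 24 (0.86), abscisic acid genes 2 higher and 2 lower of 7 (0.94), WRKY factors 2 higher and none lower of 6 (0.26) and photosynthesis genes 1 higher of 5 (0.26). None of the secondary-wall cellulose synthases was called, with CESA4 at 4187 ± 168 against 4103 ± 58.7 in T65, while all 3 primary-wall ones fell, with a median of -0.27. Of these CESA8 fell by 0.43 ± 0.06, and the calls of CESA1 and CESA3 were lost under 1 and 6 other settings. Of 4 KNOX genes 3 fell (camera adjusted p = 0.069), with OSH1 at 369 ± 35.9. The senescence genes SGR and NYC1, of chlorophyll breakdown, fell (-1.66 ± 0.09 and -1.29 ± 0.08).

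Clock transcripts moved in slr1 as well: PCL1 fell from 481 ± 66.9 to 11.9 ± 10.9 and PRR1 changed by -1.94 ± 0.08, while LHY was not called (0.18 ± 0.06, adjusted p = 0.057). The largest rises included CIPK14 (3.47 ± 0.08), the glutaredoxins GRXC1 (3.21 ± 0.11) and GRXC15 (2.68 ± 0.07), and LIS, a terpene synthase (2.78 ± 0.11); the largest falls included ABCG45, a transporter (-3.76 ± 0.39), ASMT, of melatonin synthesis (-3.52 ± 0.08), and MT1B, a metallothionein (-3.28 ± 0.08). Of the probe sets, 5202 were higher and 6178 lower in slr1 than in T65. Of these 11380, 2551 changed at least 2-fold, and among them the split turned to 1335 higher and 1216 lower. Centred on the spiked controls, with a median log2 change of -0.11, the split was 3552 higher and 6845 lower; centred on array medians only 7348 were called.

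**Figure D3:**
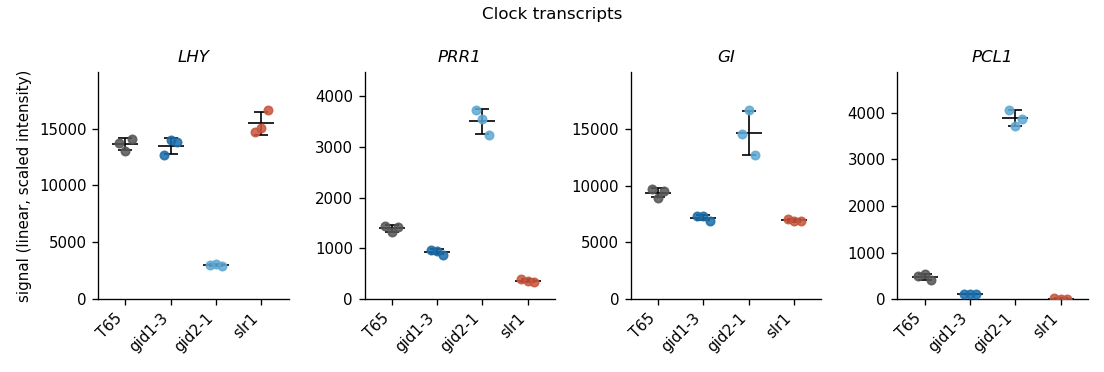
Signal (linear scaled intensity, y axis) of 4 clock genes in each line (x axis), with points for the 3 arrays and bars for the mean ± SD. LHY averages 2994 in gid2-1 against 13630 in T65, and PRR1 and PCL1 are highest in gid2-1 and lowest in slr1. GI is highest in gid2-1, and its arrays of gid1-3 and slr1 overlap below T65.

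Lists not yet described gave few calls or mixed directions. The 6 clock genes counted 3 lower in gid1-3, 3 higher and 2 lower in gid2-1, and 1 higher and 3 lower in slr1 (camera adjusted p = 0.31, 0.68 and 0.42); PRR95 fell in all 3 mutants, and the rise of PRR73 in slr1 was lost under 4 other settings. The 5 brassinosteroid genes counted 1 higher and 1 lower in gid1-3, 1 and 2 in gid2-1, and 1 and 1 in slr1 (0.55, 0.78 and 0.96), with BRD1, a late synthesis enzyme, lower in each; the rise of BZR1, a transcription factor of this pathway, was lost under 6 other settings in gid1-3 and under 2 in gid2-1. Of the 3 strigolactone genes, D17 fell and D14 rose in gid1-3, and D14 and D3 rose in slr1; the rise of D14 in gid1-3 was lost with arrays centred on the spiked controls. The 18 cytokinin genes counted 4 higher and 5 lower in gid1-3, 5 and 6 in gid2-1, and 4 and 5 in slr1 (0.87, 0.89 and 0.79), the last becoming 5 and 4 after quantile normalization. The 13 ethylene genes counted 4 higher and 3 lower in gid1-3, 5 and 1 in gid2-1, and 5 and 1 in slr1 (0.56, 0.42 and 0.26), the first becoming 3 and 4 after quantile normalization; ACS2, of ethylene synthesis, rose in all 3 mutants. The 24 ribosomal protein genes counted 6 higher and 1 lower in gid1-3, 5 and 2 in gid2-1, and 3 and 2 in slr1 (0.21, 0.54 and 0.86); centred on the spiked controls the first 2 pairs turned to 2 and 4, and 2 and 3, and after quantile normalization the first turned to 3 and 5 and the last to 3 and 6. The 5 alpha-amylases counted 2 higher in gid1-3, 3 higher in gid2-1, and 1 higher and 1 lower in slr1 (0.24, 0.42 and 0.73), with AMY3D higher in all 3 mutants. The fall of amy2A in slr1 was lost under 14 other settings and the rise of AMY1A in gid2-1 under 5. The 5 lipid transfer proteins counted 1 lower in gid1-3, 3 lower in gid2-1 and 1 higher in slr1 (0.69, 0.42 and 0.74); LTPL1 and LTP110-A in gid2-1 and LTPL1 in slr1 lost their calls with arrays centred on their medians. Of 6 floral transition genes MADS18 fell in gid1-3 and slr1, and MADS50 in gid2-1 and slr1 (0.49, 0.89 and 0.42). Of 4 root markers NRAMP5 fell in both gid mutants and Lsi1 rose in gid2-1 and slr1 (0.58, 0.78 and 0.85). Of the 3 peroxidases, 2 rose and PRX74 fell in gid1-3, PRX112 rose and PRX74 fell in gid2-1, and PRX74 rose in slr1; all 3 of the rises in gid mutants were lost with arrays centred on the spiked controls. The only xyloglucan endotransglucosylase, XTH8, rose in gid2-1 and slr1, the former call lost with arrays centred on their medians or on the spiked controls. Median and mean differed in sign for clock genes (0.29 and -0.01) and core histones (0.02 and -0.02) in gid2-1, ribosomal proteins in slr1 (-0.05 and 0.02), lipid transfer proteins in gid1-3 (0.04 and -0.10) and slr1 (0.01 and -0.07), strigolactone genes in gid1-3 (0.35 and -0.37) and gid2-1 (0.18 and -0.05), and peroxidases in gid1-3 (0.44 and -0.51), gid2-1 (0.37 and -0.15) and slr1 (-0.12 and 0.05). The test pointed down for floral genes in gid2-1 at a median of 0.23 and up for root markers in slr1 at -0.04. NYC1 rose in both gid mutants, a call lost in gid1-3 with arrays centred on the spiked controls.

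The direct comparison of gid1-3 with gid2-1 tests whether the 2 lines, mutants of the receptor and of the F-box protein, differed in transcript levels. Each line is a single group and their clock genes differed. A difference in time of harvest and an effect of the mutations therefore cannot be told apart. All 6 listed cellulose synthases were lower in gid1-3 than in gid2-1. CESA4 measured 435 ± 43.4 in gid1-3 and 1720 ± 96.8 in gid2-1, and CYCB1-1 measured 257 ± 24.2 and 939 ± 67.2. HSP24.1 was 33.1-fold higher in gid1-3 (2863 ± 90.3 against 87.7 ± 17.6), and PSAG 8.18-fold higher.

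All 3 secondary-wall and all 3 primary-wall cellulose synthases were lower in gid1-3 than in gid2-1, with medians of -1.99 and -0.89. Expansins counted 17 lower and 1 higher of 29, also adjusted over the list alone (camera adjusted p = 0.00048; adjusted p = 0.075 with an estimated correlation). Cyclins and CDKB counted 10 lower and none higher of 17, also adjusted over the list alone (0.0065; adjusted p = 0.075 with an estimated correlation). Tubulins counted 7 lower of 10, also adjusted over the list alone (0.01; adjusted p = 0.098 with an estimated correlation; 0.094 with a gene's probe sets averaged). Of 4 KNOX genes 3 were lower, also adjusted over the list alone (0.041; adjusted p = 0.25 with an estimated correlation, and 0.053 to 0.069 under 8 other settings). Heat shock genes counted 10 higher and 1 lower of 23, also adjusted over the list alone (0.01; adjusted p = 0.075 with an estimated correlation). The clock genes differed here too, with PCL1 32.9-fold lower in gid1-3 (-5.04 ± 0.41) and LHY higher by 2.17 ± 0.06. Monolignol and laccase genes counted 10 lower and 2 higher of 24 (0.35), replication licensing 5 lower of 9 (0.27) and core histones 3 lower of 5 (0.21). The phytoalexin and jasmonate lists were not called as sets (0.75 and 0.35). Of the probe sets, 5182 were higher and 6864 lower in gid1-3 than in gid2-1, and 3572 of these 12046 differed at least 2-fold. Centred on array medians the split turned to 4943 higher and 3975 lower.

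Set against the mean of both gid mutants, slr1 tests whether the repressor mutant differed from the mutants of the receptor and the F-box protein. The T65 mean does not enter this contrast, though the T65 arrays enter the estimate of spread, and the contrast does not show on which side of T65 a line lay. All 6 listed cellulose synthases were higher in slr1, and most phytoalexin genes were lower. CESA7 measured 4367 ± 1090 in slr1, 376 ± 117 in gid1-3 and 1241 ± 167 in gid2-1, EXPB2 was 11.3-fold higher in slr1, and TUBB8 measured 4808 ± 561 against 854 ± 102 and 2156 ± 169. The jasmonate gene LOX9 was 8.53-fold lower (925 ± 50.4 in slr1, 7797 ± 88.5 and 7986 ± 533 in the gid mutants), and MS was 8.64-fold lower. The jasmonate list counted 16 lower and 8 higher of 35, or 18 lower and 8 higher adjusted over the list alone (camera adjusted p = 0.06; adjusted p = 0.33 with an estimated correlation; 0.031 with arrays centred on their medians).

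Here 4 list calls held with an estimated correlation. Of 11 phytoalexin genes 9 were lower and 1 higher, or 10 lower adjusted over the list alone (camera adjusted p = 0.00033; adjusted p = 0.041 with an estimated correlation). Expansins counted 16 higher and 1 lower of 29, tubulins 8 higher of 10 and heat shock genes 14 higher and 2 lower of 23, all also adjusted over the list alone (camera adjusted p = 0.0015, 0.00033 and 0.0052; adjusted p = 0.041 for each with an estimated correlation). Calls lost with an estimated correlation were those of replication licensing, 7 higher of 9 (0.006; adjusted p = 0.12 with an estimated correlation), core histones, 5 higher of 5 (0.014; 0.16), auxin genes, 13 higher and 3 lower of 27 (0.037; 0.15), monolignol and laccase genes, 14 higher and 5 lower of 24 (0.046; 0.15), and cyclins and CDKB, 9 higher and 2 lower of 17 (0.046; 0.15). Adjusted over the list alone these counts were the same except for 3 cyclins lower; the last 2 calls were each lost under 10 other settings and that of the auxin genes under 2. All 3 secondary-wall cellulose synthases were higher in slr1, with a median of 2.52, and the KNOX genes counted 1 higher and 3 lower of 4 (camera adjusted p = 0.26). Of the probe sets, 7958 were higher and 9187 lower in slr1. Of these 17145, 5431 differed at least 2-fold, and among them the split turned to 3082 higher and 2349 lower. Centred on the spiked controls the split turned to 9118 higher and 6142 lower.

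**Figure D4:**
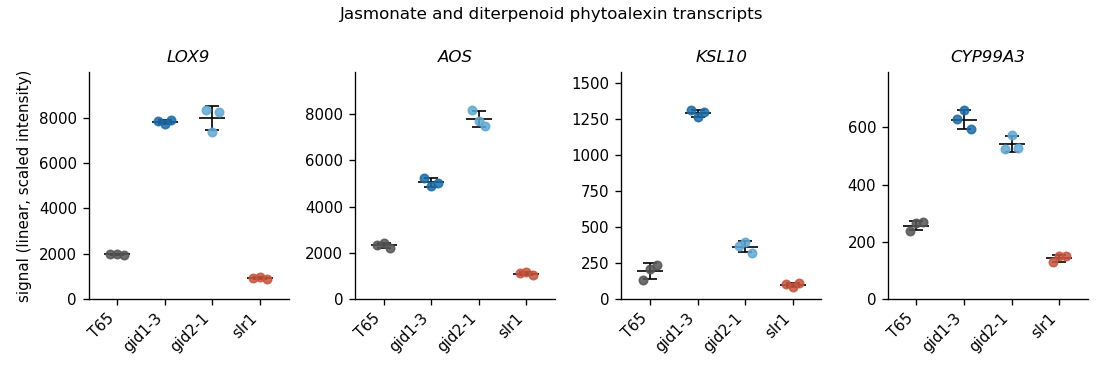
Signal (linear scaled intensity, y axis) of the jasmonate genes LOX9 and AOS and the phytoalexin genes KSL10 and CYP99A3 in each line (x axis), with points for the 3 arrays and bars for the mean ± SD. All 4 lie above T65 in both gid mutants and below it in slr1, with LOX9 at 7797, 7986 and 925 against 1972 in T65. In the whole jasmonate list more members rose than fell in slr1.

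Genes called in all 3 mutants included some that moved in opposite directions in the gid mutants and slr1. EXPB11 measured 868 ± 73.9 in T65, 123 ± 18.6 in gid1-3, 318 ± 14.7 in gid2-1 and 1607 ± 61.6 in slr1. LAC10, a laccase, measured 1173 ± 13.4, 250 ± 19.4, 524 ± 53.5 and 1947 ± 60.5, and RAB21, a dehydrin, 731 ± 30.1, 257 ± 27.2, 195 ± 38.0 and 1569 ± 84.6. In the other direction, another laccase, LAC24, measured 1380 ± 53.5 in T65, 3885 ± 74.2 in gid1-3, 3578 ± 196 in gid2-1 and 322 ± 21.5 in slr1. LOX9 and AOS of jasmonate synthesis and KSL7, KSL10 and CYP99A3 of phytoalexin synthesis were also higher in both gid mutants and lower in slr1. LOX9 and AOS do not stand for the jasmonate list, of which more members rose than fell in slr1.

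In all, 554 probe sets were lower in both gid mutants and higher in slr1, and 601 were the reverse. Independent lists would give 100 and 119, but with the overlap of the gid mutants taken as given they would give 452 and 584. A larger number moved the same way in all 3 mutants: 2293 were higher and 2053 lower, against 492 and 537 with that overlap taken as given. Of the 5501 probe sets called the same way in both gid mutants and also called in slr1, 21.0% had the opposite sign in slr1. The number with opposite signs, 1155 in all, fell to 590 with arrays centred on their medians and to 738 without a trend in the prior variance.

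The gid mutants shared most of their calls. CIPK14, GLT2 and BURP16 rose in both, and CRSH2 fell from 3923 ± 92.4 in T65 to 135 ± 37.3 in gid1-3 and 102 ± 36.2 in gid2-1. Of the 11077 probe sets called in both, 5407 were higher in both, 4973 were lower in both and 697 had opposite signs, against 1105, 1094 and 2209 for independent lists. The log2 changes of gid1-3 and gid2-1 correlated across the 28597 brighter probe sets with r = 0.698, those of gid1-3 and slr1 with 0.353 and those of gid2-1 and slr1 with 0.311. Simulated unchanged groups gave 0.501, 0.499 and 0.499 through the shared control alone. That r arises however small the noise is, so it is not a chance level for lines that changed, and the lower r with slr1 cannot be read against it. The covariances (0.490, 0.181 and 0.141) lay above the simulated 0.0175, 0.0174 and 0.0174. Genes are not independent replicates. Among the 4637 probe sets called the same way in both and different between them, gid1-3 lay farther from T65 in 62.6%. Over the 4 lines, 22829 probe sets differed by limma's F-test.

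**Figure D5:**
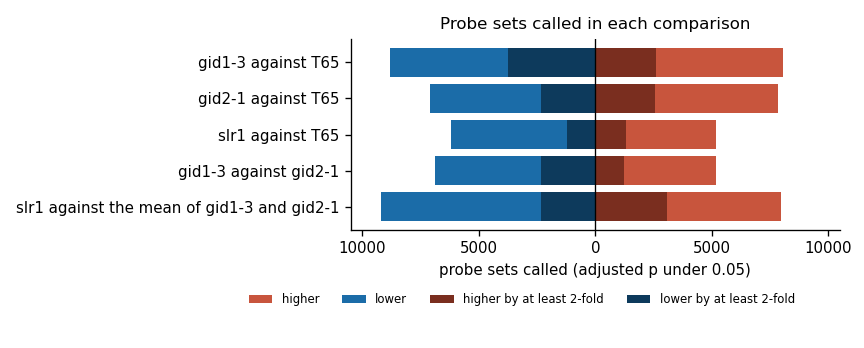
Number of probe sets called higher (right) and lower (left) at an adjusted p under 0.05 (x axis) in each of 5 comparisons (y axis), with the part that changed at least 2-fold in darker shades. The comparison of slr1 with T65 has 11380 calls and that of gid1-3 with T65 has 16878.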

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

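All tests of the second pattern were chosen or revised after the result was seen, and so were the centring on spiked controls and the reading of LIR1 and of the fungal probe sets as not deciding.

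The lines differed in ways that their shared control does not show. Between gid1-3 and gid2-1 12046 probe sets differed, and 697 were called in opposite directions against T65 with the mutants also different from each other. The named genes with the largest such differences, as gid1-3 minus gid2-1 on the log2 scale, were HSP24.1 (5.05), PCL1 (-5.04), EXPB18 (-4.49), SAPK9 (-3.66), CLPB-M (3.51) and BURP2 (3.45); EXPB18 lay below the reporter level in gid1-3, so its size is not resolved.

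Of 133 control probe sets for transcripts neither of rice nor among the spiked controls used for centring, 7 were called above T65 over the 3 mutants. Only rises were listed. Among all 57194 tested probe sets rises were far more frequent, with 8068 in gid1-3, 7836 in gid2-1 and 5202 in slr1. The 133 include the reporter controls and were not sorted by whether they are other added controls. On probe sets for the blast fungus Magnaporthe, log2 signal was higher by 2.88 (ef1a, middle part) in gid1-3, and by 3.19 (ef1a, 3' part) and 2.31 (gapdh, 3' part) in gid2-1. Probe sets for bacterial phe and lys transcripts were higher by 2.77 in gid1-3 and by 3.27 in slr1, and those for the synthetic tags TagE and TagIN by 2.64 in gid2-1 and by 2.08 in slr1. The T65 means of all 7 lay below the reporter level of the T65 arrays (35.4 to 42.0), and in the mutants only the 3 of Magnaporthe rose above the highest reporter level of any array (52.2), so the sizes are not resolved. The brightest went from 14.4 ± 3.16 in T65 to 104.8 ± 11.9 in gid1-3 (n = 3). The spiked controls, 27 probe sets, lay above T65 by 0.22 in gid1-3, 0.20 in gid2-1 and 0.09 in slr1.

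The first pattern weighed is the clock genes of gid2-1, with LHY lower and PRR1, GI and PCL1 higher than in T65. A single scaling factor per array of the size of the spiked controls' shift is argued against. Such a factor lowers every log2 change of gid2-1 by about 0.20, so it cannot move LHY down and PRR1, GI and PCL1 up. After this subtraction the smallest change of the 4, that of GI, was 0.44 ± 0.09 with its sign kept. The subtraction does not bear on other kinds of scaling. A harvest of gid2-1 at a later time of day may account for it: LIR1, a light-regulated transcript chosen before its value was seen, was higher in gid2-1 by a log2 change of 1.00 ± 0.10, as that explanation needs. However, LIR1 was as high in gid1-3 (0.91 ± 0.10; difference -0.09 ± 0.10), where PRR1, GI and PCL1 fell, so after the values were seen LIR1 was read as not deciding. A time of harvest and an effect of the mutation on the clock cannot be told apart, because the labels give no time and each line is a single group.

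The second pattern is that among probe sets called the same way in both gid mutants and also in slr1, 4346 had the same direction in slr1 and 1155 the opposite. Chance values of the shared T65 arrays are argued against as the cause, since with 1 T65 array as the control of the gid mutants and the other 2 as that of slr1 the ratio of same to opposite probe sets was still 3.96 to 4.24, as with 2920 against 738 where independent lists would give 595 and 601. Scaling of the T65 arrays stays open. With arrays centred on their medians the ratio was 4.45, with 1416 higher and 1210 lower in all 3 mutants. That centring moved the median log2 change from -0.0045 to 0.049 in gid1-3 and from 0.049 to -0.014 in gid2-1. In slr1 it went from -0.017 to -0.028. Shifts this small could hardly turn the ratio, so larger shifts and other kinds of scaling are not addressed. The test written first, centring on the spiked controls, gave a ratio of 5.22. It was set aside because that centring lowers all 3 mutants against T65. A T65 harvest at another time of day stays open: 3 of 4 clock genes were called in opposite directions in different mutants, but LIR1 was higher and PRR95 lower in all 3, and the mutants need not share a time of harvest. Another difference in how T65 was grown, and a shared effect of the mutations, stay open and were not tested.

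The third pattern is that 21 members of the phytoalexin and jasmonate lists were called higher in both gid mutants; as sets the phytoalexins did not pass in gid1-3, and the other 3 list calls were lost with an estimated correlation. A single scaling factor of the size of the spiked controls' shift is argued against for most of these members. With arrays centred on those controls 17 (81%) stayed so, close to the bound of 80% set beforehand. The median change of the 21 went from 1.09 to 0.87 in gid1-3 and from 1.40 to 1.21 in gid2-1, as a subtraction of 1 amount per line brings. Other kinds of scaling are not addressed by it. Scaling stays open for the other 4. RNA of the blast fungus stays open: 0 of its 10 probe sets lay above the reporter level on all 6 gid arrays and on no T65 array, which was to exclude it, but these probe sets are dim, 9 had a higher mean in gid1-3 and 10 in gid2-1 than in T65, and 8 lay above that level on at least 1 gid array against 1 on at least 1 T65 array. The counts on at least 1 array set 6 gid arrays against 3 T65 arrays, so the gid side had more chances. Some of the 10 probe sets are parts of the same transcript, so they are not independent. Another infection or stress and an effect of the mutations stay open, and PR10a, a defence marker, was lower in gid1-3.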

How the results depend on the processing

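Centring on the spiked controls was chosen after the data were seen; the other settings were planned. No probe set called in the 5 comparisons was called in the opposite direction under any setting that was run. A threshold of 2-fold left 6385 calls for gid1-3, 4919 for gid2-1 and 2551 for slr1 against T65, 3572 between the gid mutants, 5431 for slr1 against their mean, 9206 for the F-test, 2656 shared by the gid mutants, 63 with opposite signs in slr1, and 253 of the 499 gene values named by the rule (428 without it), as its construction brings. Array median centring gave 7348 calls for slr1 against T65 and 590 with opposite signs, and no trend in the prior variance gave 738 with opposite signs; the cause was not tested. The number of list calls went from 27 to 4 with an estimated correlation and to 111 with fry, which does not compare a set with other genes.

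With each array left out in turn, calls ran from 15032 to 17382 (gid1-3), 13041 to 15190 (gid2-1), 9421 to 11992 (slr1), 10507 to 12275 (gid1-3 against gid2-1), 14954 to 17204 (slr1 against the gid mean) and 21431 to 22615 (F-test), with 9025 to 10542 shared, 839 to 1221 of opposite sign, 24 to 28 list calls and 413 to 430 named values. With a replicate block, gid1-3 against T65 gave 8019 higher and 8742 lower. Of 10900 named gene values over all settings, 10482 kept their side of the threshold and direction, 371 lost a call and 46 gained one. RPS7 in gid1-3 turned from 0.209 to -0.0107 when centred on the spiked controls, which lowers every change of gid1-3 by 0.22. Of 3100 list values 2939 kept their side, 58 lost a call and 103 gained one. The F-test with only the arrays compared, and the lists with a 2-fold threshold, give no value. Between arrays, 54.7 to 63.1% of probe sets lay above the reporter level, and small changes are not resolved in the rest.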

Other observations

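The aquaporins were taken as a group after their values were seen; the splits of the samples were planned.

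Aquaporins were in no list fixed beforehand, and no test of the group was run. Of 22 measured aquaporins, 12 fell and 1 rose in gid1-3, 12 fell and 3 rose in gid2-1, and 8 fell and 3 rose in slr1, all against T65. PIP2-2 measured 14760 ± 361 in T65, 4393 ± 133 in gid1-3, 2035 ± 82.3 in gid2-1 and 15320 ± 399 in slr1 (n = 3). PIP2-4 measured 1819 ± 49.7, 244 ± 17.6, 57.2 ± 9.40 and 406 ± 40.4. Lsi6, a silicon channel of the shoot, measured 6686 ± 431, 862 ± 62.2, 2124 ± 123 and 6006 ± 156. TIP2-2 went the other way, with 9234 ± 263 in T65, 14720 ± 508 in gid1-3, 11480 ± 566 in gid2-1 and 19630 ± 753 in slr1. The group was not run under other scalings.

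Other splits of the samples were run for each count. For the 3 comparisons with T65 and for gid1-3 against gid2-1, 1 of the 10 splits of 6 arrays gave as many calls, the real one, with 16878, 14939, 11380 and 12046 calls against 0 in the highest other split; 10 splits are too few for a share under 0.05. Chance can be excluded for the F-test (22829, highest other 5849), where 1 of 100 splits, the real one, gave as many. For slr1 against the gid mean it was also 1 of 100 (17145, highest other 12073). Those splits mix gid1-3 with gid2-1 as well, which differ. They bear on whether the 3 mutants are all alike, not on the contrast of slr1 with the gid mean. For the calls shared by the gid mutants it was also 1 of 100 (10380, highest other 1814). Splits that mix the lines also change the calls of each comparison, so that count does not bear on chance overlap of the lists. For that overlap 1105 higher and 1094 lower were expected of independent lists, against 5407 and 4973 seen. For calls of opposite sign in slr1 it was also 1 of 100 (1155, highest other 0), but the splits that mix the lines gave none, so this does not bear on chance overlap of the lists, for which 452 and 584 were expected against 554 and 601 seen. Chance cannot be excluded for the number of list calls, since 6 of 100 splits gave as many as the 27 observed, with 29 in the highest other split.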
